A study of Mus musculus with 18 samples.

How the data were processed

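RNA was measured in 18 mouse cochlear libraries. Per the labels' protocols, epithelium was separated from mesenchyme and neurons, RNA was amplified as cDNA with a SMARTer V4 kit from 2.5 ng, sheared, made into libraries with a ThruPLEX kit and sequenced as single-end reads of 75 bp. The kits described there do not mark the strand, so reads from overlapping antisense genes cannot be told apart. A treatment protocol in the labels, with tamoxifen and a beta-catenin allele, matches no sample title and was not used to group samples. Groups and replicate numbers were taken from the sample titles, giving 9 groups of 2.

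The deposited files hold 1 TPM value per gene and library, which the authors scaled so that each library sums to 1000000. STAR, Salmon, FastQC and DESeq2 and the mouse build mm10 are named, without versions or roles, per the submitters' processing notes. The annotation, filters and the step from transcripts to genes are not given in the sources used here. TPM divides by gene length and by the library's total, so it keeps no depth, a rise in a few abundant genes lowers the others, and very short genes such as microRNA genes reach high values from few reads. Depth and counting error are therefore unknown, and no intervals or floors are given. None of 12 housekeeping genes was at 0 in any library.

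The files list 47729 gene identifiers. Of these 47224 matched a gene name, and the 505 without one took 0.781 to 3.76% of the TPM. Coordinates are from GENCODE mouse release M21, on the same build as the files. The TPM values were changed to log2(TPM + 1), and genes with at least 1 TPM in at least 2 of the 18 libraries were kept, 20463 in all. A log2 difference on this scale understates the change of low genes.

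Differences were tested with limma 3.58.1 in R 4.3.3 (linear model with a mean per group, moderated with a trend), in 1 fit of all 18 libraries. The fit has 9 residual and 2.8 prior degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method per comparison with a threshold of 0.05. Because all groups share 1 estimate of the spread, genes that vary between culture replicates also carry that spread into comparisons of native cells. In the other direction, a group with both libraries at 0 adds no spread. Genes listed at 0 in many groups can therefore pass with a small SE. Count models were not used, since the files hold no counts. Tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. There were 11 comparisons: the Atoh1 sort against the mean of the Lgr5 and Sox2 sorts, these 2 sorts against each other, D2, D4 and D10 against D0 in unsorted cultures, D10 against D0 in sorted cultures, sorted against unsorted at D0 and D10, both sorted culture groups against a native sort, and the difference between the 2 changes from D0 to D10.

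The 17 gene lists were written before the data were examined: hair cell transcription factors, hair bundle and mechanotransduction, hair cell synapse, channels and calcium, supporting cell, Notch pathway, Wnt pathway, cell cycle, chromatin regulators, and markers of mesenchyme, neurons, glia, immune cells, erythroid cells, endothelium, other cochlear epithelium and melanocytes, and dissociation stress. Each was tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusted over the 17 lists in a comparison. Where a list's call held with an estimated correlation, this is said beside it. The named genes follow a rule fixed at the same time. It takes, per comparison, the 6 highest and 6 lowest log2 differences among genes past the threshold whose libraries do not overlap and whose higher group averages at least 10 TPM, leaving out ribosomal protein genes and genes without a standard name. It adds 2 to 4 members of each list, those past the threshold with the largest differences and the most abundant member not past it, and Atoh1, Lgr5, Sox2, Mki67, Myo7a and Pou4f3. Oc90 in the comparison of the Lgr5 and Sox2 sorts and the genes of the closing section were named after their values were seen. Some genes that the rule takes are not reported. Values are given as mean ± SD of the 2 replicates.

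On simulated data made from these libraries, the test of the Atoh1 sort against the supporting cell sorts recovered 17% of 100 genes changed by 1 on the log2 scale and 66% of 100 changed by 2, with 5 false calls among 20263 unchanged genes. For LCP D10 against D0 it recovered 6% and 50%, with 5 false calls, and for sorted LCP D10 against D0 9% and 50%, with 7 false calls. A simulated shifted list gave a camera p of 1.14e-18, and 0 of 20 random lists passed. The simulated genes vary independently, while the real bundle list had an estimated correlation of 0.576. The list check therefore says nothing of false calls among correlated lists. The simulated libraries also vary independently, with 1 spread per gene in all groups and no other group differences. In the real data, deviations of same-numbered unsorted LCP libraries correlated at 0.211 to 0.483. The median absolute log2 difference between replicates ran from 0.3056 (Atoh1 sort) to 0.4625 (sorted LCP D0). The counts of false calls thus hold only for the simulated setting. The changed genes had a mean log2(TPM + 1) above log2(6), so recovery of low genes was not simulated.

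The labels give 3 sequencing dates. All replicates numbered 2 share 1 date, and those numbered 1 fall on 2 dates, with unsorted D0, D2 and D4 on one and the rest on the other. Each date holds at most 1 library of a group, so within a date there is no spread between replicates, and fits with the replicate number as a block and with the date as a covariate were made. Only the date covariate compares groups within dates, since the block sets unsorted D0, D2 and D4 against the other groups across dates for replicate 1. Over 18 pairs of groups whose numbers share dates, the deviations of same-numbered libraries correlated at -0.019 to 0.483 (median 0.106), above 0.1 in 9. The 6 pairs among the unsorted LCP groups, of which 3 share dates for both numbers, correlated at 0.211 to 0.483. Same-numbered unsorted libraries thus deviate together, which the tests of D2, D4 and D10 against D0 leave in the error. With the sorted LCP groups the unsorted groups correlated at only -0.019 to 0.091. The block is 1 replicate effect over all 9 groups, so it removes only the part that all groups share. A block for the unsorted groups alone was not fitted. Extraction dates in the labels lie after the sequencing date for 7 libraries, so those dates were not used. The labels' protocol states that a sample came from one animal. For the cultures it is not given in the sources used here whether replicates came from separate cultures, and p-values then measure only the spread between these samples, which may be technical.

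Alternatives were set before the data were examined: a pseudocount of 0.1, no filter, a filter of 5 TPM in 2 libraries, the replicate block, the date covariate, median ratio scaling, quantile normalization, array weights, the groups compared alone, and leaving out each replicate. For the genes that separate the native sorts, no minimum log2 difference and an estimated correlation were added to these. The protein-coding genes alone, each supporting cell sort alone, and the native genes held fixed under the block and the pseudocount were added after seeing the data. Comparisons between D2, D4 and D10 share the D0 libraries, so their overlaps and correlations were not computed.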

Results

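Transcript abundance was measured by RNA sequencing in 18 libraries from mouse cochlea, in 9 groups of 2 replicates. Cells sorted from native tissue at postnatal day 2 made up 3 groups. The Atoh1 sort is taken as native hair cells, the mechanosensory cells of the cochlea. The Lgr5 and Sox2 sorts are taken as native supporting cells, the neighboring epithelial cells. Hair cell transcripts were present in these 2 sorts too, so the names stand for the sorts and not for pure cell types. The other groups are LCP cultures, expanded and then differentiated. LCP is read here as Lgr5-positive cochlear progenitors, a name that is not spelled out in the sources used here. Unsorted cultures were sampled at D0, D2, D4 and D10 of differentiation, and sorted cultures at D0 and D10. The sort used on the cultures is not given in the sources used here. Values were deposited as TPM (transcript abundance scaled to a fixed total per library), which keep no depth, so the read depth per sample is unknown and no counting interval can be given. Between 14381 and 16713 genes reached 1 TPM in a library, and mitochondrial genes took 4.27 to 12.7% of the TPM. Replicates correlated at Pearson's r of 0.9033 (LCP D10) to 0.9455 (sorted LCP D10) across genes, which are not independent replicates.

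The genes that define the sorts and the main cell states were looked at first. Atoh1, the transcription factor that starts hair cell differentiation (chromosome 6, 64729125 to 64731245, mm10), was at 135 ± 37.2 TPM (SD, n = 2) in the Atoh1 sort, 54.4 ± 25.7 in the Lgr5 sort and 67.2 ± 25.4 in the Sox2 sort. It was at 0.343 ± 0.471 TPM in sorted LCP D0 and 29.5 ± 2.83 in sorted LCP D10. Pou4f3, a hair cell transcription factor, was at 71.4 ± 7.56 TPM in the Atoh1 sort, 0.0332 ± 0.0469 in sorted LCP D0 and 53.4 ± 4.49 in sorted LCP D10. Lgr5, a Wnt target and progenitor marker (chromosome 10, 115450311 to 115587780), was at 37.4 ± 10.2 TPM in its own sort, 22.5 ± 14.2 in the Atoh1 sort and 35.5 ± 12.1 in the Sox2 sort. Sox2 (chromosome 3, 34650405 to 34652461) was at 92.8 ± 66.6 TPM in the Lgr5 sort and 42.3 ± 21.3 in the Sox2 sort. Mki67, a proliferation marker, was at 7.55 ± 4.85 TPM in sorted LCP D0, 4.95 ± 0.285 in unsorted LCP D0 and 0.0755 ± 0.022 in the Lgr5 sort. None of the differences in Atoh1, Lgr5 and Sox2 between the native sorts passed the test, the smallest adjusted p being 0.472.

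**Figure D1:**
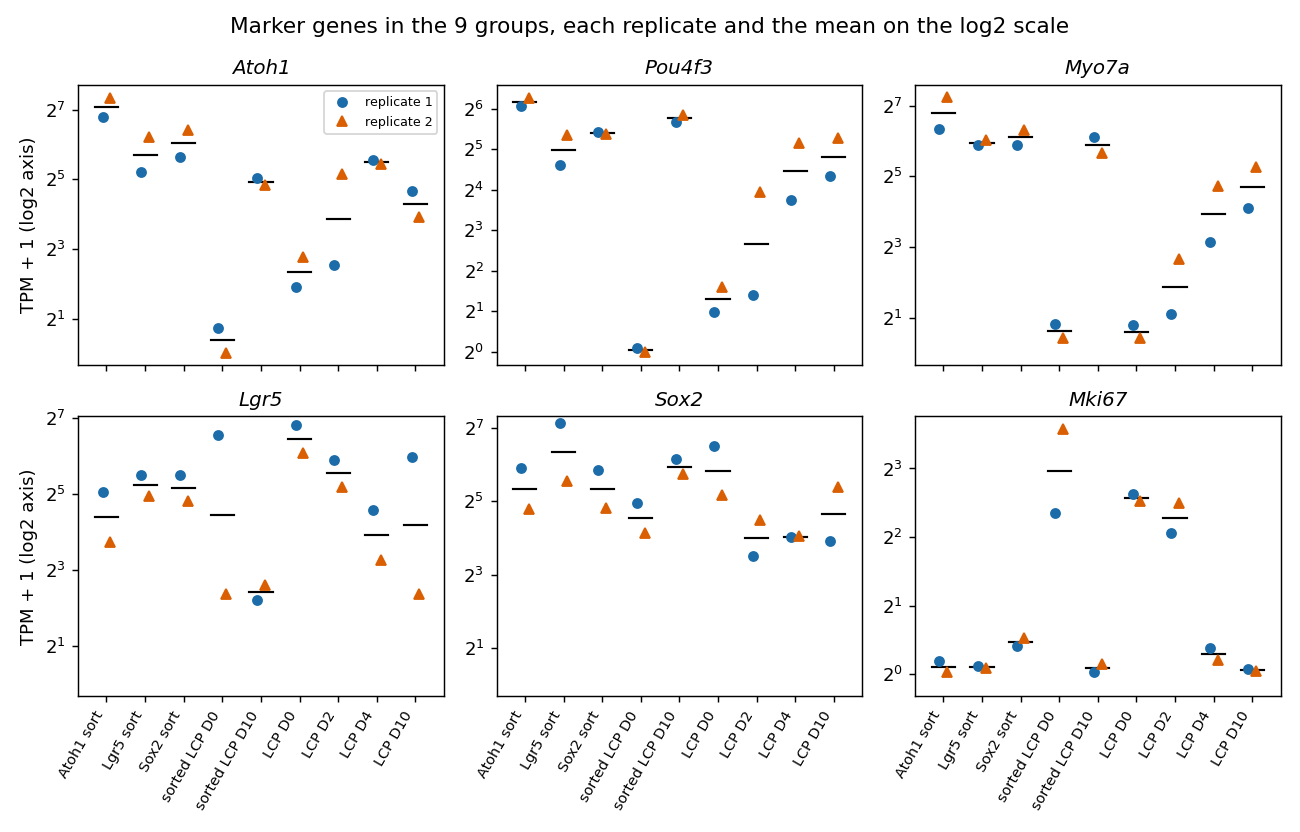
TPM + 1 on a log2 axis for Atoh1, Pou4f3, Myo7a, Lgr5, Sox2 and Mki67 in the 9 groups. Circles are replicate 1, triangles replicate 2, and bars the mean on the log2 scale of the 2 replicates; Lgr5 in sorted LCP D0 and in LCP D10 shows the widest gaps between replicates.

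The first comparison asked which genes separate native hair cells from native supporting cells. Slc26a5, which encodes prestin, the motor protein of outer hair cells, was higher in the Atoh1 sort (15.3 ± 3.88 TPM) than in the supporting cell sorts (log2 difference 1.82, SE 0.36, adjusted p = 0.0416). Bmp4 and Gata2, expressed in cochlear epithelium outside the hair cells, were lower in the Atoh1 sort by log2 differences of -3.87 (SE 0.42, adjusted p = 0.00108) and -3.43 (SE 0.33, adjusted p = 4.61e-04). Car3, a carbonic anhydrase, was higher (log2 difference 3.16, SE 0.39, adjusted p = 0.00331). In all, 168 of 20463 genes differed, 65 higher and 103 lower in the Atoh1 sort.

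Further genes higher in the Atoh1 sort were Defa2, Defa32, Ppme1 and Rtel1, with log2 differences of 5.98, 3.31, 1.98 and 1.74. Defa2 and Defa32 belong to a family of near-identical defensin genes, so the split of reads between them is uncertain. Pmch (log2 difference -4.43) and Npnt (-3.43) were lower, as were the short microRNA genes Mir8114 (-3.44) and Mir199a-1, whose TPM rests on few bases. Mir199a-1 was listed at 0 in the Atoh1 sort and at 13.1 TPM in the supporting cell sorts. In the 3 hair cell lists, transcription factors had 0 of 10 genes past the threshold (1 adjusted over the list alone), bundle and mechanotransduction genes 0 of 34 (0 adjusted over the list alone) and synapse, channel and calcium genes 1 of 17 (1 adjusted over the list alone). Camera called the 3 lists higher (adjusted p = 0.000725, 5.57e-09 and 3.43e-06), with adjusted p = 0.276, 0.296 and 0.276 with an estimated correlation and 0.113, 0.131 and 0.113 by fry. The supporting cell list had 0 of 22 members past the threshold (6 lower adjusted over the list alone) and a camera adjusted p of 5.34e-06, with adjusted p = 0.276 with an estimated correlation. The glia list was lower (1 of 7 members, 5 adjusted over the list alone, camera adjusted p = 1.3e-08), and kept its call with an estimated correlation (adjusted p = 0.00497). The list of other cochlear epithelium markers was lower too (2 of 9 members, 2 adjusted over the list alone, camera adjusted p = 1.89e-06), with adjusted p = 0.0303 with an estimated correlation.

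Hbb-bs, a hemoglobin gene, was at a log2 difference of 3.72 (SE 1.27, adjusted p = 0.246), and 0 of 5 erythroid markers passed over all genes (4 higher adjusted over the list alone). The camera adjusted p of the erythroid list was 0.000502, with adjusted p = 0.276 with an estimated correlation. The Wnt list was lower by camera (adjusted p = 0.00597; with an estimated correlation adjusted p = 0.339) with 0 of 17 members past the threshold. No member of the Notch, cell cycle, chromatin, mesenchyme, neuron, immune, endothelium, melanocyte and dissociation stress lists passed, and camera called none of these 9 lists. With the replicate block it called the Notch list lower (adjusted p = 0.0199). Adjusted over the list alone, 1 member each of the cell cycle, neuron, immune and stress lists was higher and 1 each of the mesenchyme and endothelium lists was lower. The median of the mesenchyme list was 0.40 and its mean -0.11, and the endothelium and cell cycle lists had medians of 0.24 and -0.05 against a camera direction of the opposite sign. Without replicate 2 of the Atoh1 sort 73 genes passed, 47 higher and 26 lower, and in a fit of the 6 native libraries alone 10 did, 9 higher and 1 lower. With no filter the calls split into 181 higher and 171 lower, so whether more genes were higher or lower depends on the fit. Of 13 genes called among those named by rule, 8 kept the call in every fit without 1 library of these groups. In alternatives chosen after seeing the data, 63 genes passed against the Lgr5 sort alone (28 higher and 35 lower) and 222 against the Sox2 sort alone (61 higher and 161 lower).

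The 2 supporting cell sorts were set against each other. The myelin genes Pmp22 (log2 difference -5.09, SE 0.57, adjusted p = 0.00136) and Mbp (-4.49, SE 0.64, adjusted p = 0.00731) were lower in the Lgr5 sort. Nefh, a neurofilament gene of neurons, was lower in the Lgr5 sort (log2 difference -2.78, SE 0.40, adjusted p = 0.00842), as was Otx2 (-1.86, SE 0.35, adjusted p = 0.0397; 0.0577 with the replicate block), a marker of other cochlear epithelium. Trh, the thyrotropin-releasing hormone gene, was higher in the Lgr5 sort (28.6 against 0.0404 TPM; log2 difference 4.40, SE 0.62, adjusted p = 0.00731). Of 114 genes past the threshold, 11 were higher and 103 lower in the Lgr5 sort.

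Ubb, a ubiquitin gene, was also higher in the Lgr5 sort (log2 difference 0.95; adjusted p = 0.0518 with the replicate block), and Spock3 (-4.22) was lower. Mir27b and Mir339 were listed at 0 in the Lgr5 sort and at 30.1 and 22 TPM in the Sox2 sort, with adjusted p = 0.0619 for Mir27b with the replicate block. Of the glia list, 4 of 7 members were lower (4 adjusted over the list alone; camera adjusted p = 6.94e-09, with an estimated correlation adjusted p = 0.00441). Of the neuron list, 1 of 10 was lower (5 adjusted over the list alone; camera adjusted p = 5.26e-07, with an estimated correlation adjusted p = 0.0239). The cell cycle list had 0 of 34 members past the threshold (6 lower adjusted over the list alone) and was lower by camera (adjusted p = 6.94e-09; with an estimated correlation adjusted p = 0.246). The dissociation stress list was higher by camera (adjusted p = 2.39e-05; with an estimated correlation adjusted p = 0.313), with 0 of 16 members past the threshold. The list of other cochlear epithelium markers was lower (1 of 9, 3 adjusted over the list alone; camera adjusted p = 0.00632, with an estimated correlation adjusted p = 0.232). Oc90, a member of that list, was at 1025 ± 1041 TPM in the Sox2 sort and 21 ± 19 in the Lgr5 sort. Of 11 genes called among those named by rule, 3 kept the call in every fit without 1 of these libraries. The count was 285 without replicate 1 of the Sox2 sort, 62 without its replicate 2, 45 without replicate 2 of the Lgr5 sort, and 0 in a fit of these 4 libraries alone (1340 genes had an unadjusted p under 0.05 by limma in the fit of 18 libraries).

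The unsorted cultures were compared between days. At D2 few genes differed from D0: 10 passed, 3 higher and 7 lower, and 921 had an unadjusted p under 0.05 by limma. Gpx6, a glutathione peroxidase gene, fell by 3.20 on the log2 scale (SE 0.43, adjusted p = 0.0296) and Ube2l6, a ubiquitin-conjugating enzyme gene, fell by 2.71 (SE 0.38, adjusted p = 0.0318). Hes1, a Notch target, was at 29.5 ± 15 TPM at D2 and 1336 ± 914 at D0, a log2 difference of -5.36 (SE 1.24, adjusted p = 0.303) that did not pass, though it did with the replicate block (adjusted p = 0.0319). Atoh1 was at 19.7 ± 21 TPM at D2 and 4.28 ± 2.15 at D0 (log2 difference 1.52, SE 0.69, adjusted p = 1), also short of the threshold. Camera called the 3 hair cell lists higher (adjusted p = 3.49e-06, 1.83e-05 and 0.00108 for transcription factors, bundle and synapse, with adjusted p = 0.471, 0.63 and 0.568 with an estimated correlation). It also called the dissociation stress list higher and the mesenchyme list lower (adjusted p = 0.000786 and 0.0175, with adjusted p = 0.568 and 0.482 with an estimated correlation). The cell cycle list was lower (adjusted p = 1.25e-07; with an estimated correlation adjusted p = 0.482). Of the Notch list 0 of 16 genes passed over all genes, while 3 were higher and 6 lower adjusted over the list alone (camera adjusted p = 0.00756, with an estimated correlation adjusted p = 0.568). Both genes called among those named by rule lost the call in some fit without 1 of these libraries. The count was 12 with the replicate block, 7 without replicate 1 of LCP D2 (5 higher and 2 lower), 2 without its replicate 2, 6 without replicate 2 of LCP D0, and 0 at a filter of 5 TPM and in a fit of these 4 libraries alone.

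D4 was compared with D0 next. Cabp2, a calcium-binding protein of hair cell synapses (chromosome 19, 4081578 to 4087340), rose from 0.021 ± 0.0297 to 131 ± 144 TPM (log2 difference 6.37, SE 1.02, adjusted p = 0.00602). Kcna10, a potassium channel gene, rose by a log2 difference of 5.41 (SE 0.77, adjusted p = 0.00317), and Lhfpl5, part of the mechanotransduction complex, by 4.81 (SE 0.88, adjusted p = 0.0117). Atoh1 and Pou4f3 rose by 3.16 (SE 0.69, adjusted p = 0.0286) and 3.17 (SE 0.69, adjusted p = 0.0285). The Notch targets Hes1 (chromosome 16, 30064384 to 30067796), Hes5 and Hey1 fell, with log2 differences of -5.60 (SE 1.24, adjusted p = 0.0307), -5.42 (SE 1.33, adjusted p = 0.0489) and -4.85 (SE 0.92, adjusted p = 0.014). Of 693 genes past the threshold, 224 were higher and 469 lower at D4.

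Of the hair cell lists, 6 of 10 transcription factors rose (6 adjusted over the list alone), with Gfi1 at a log2 difference of 4.23 and Lhx3 at 4.18. Of the bundle list 16 of 34 rose (26 higher and 1 lower adjusted over the list alone), with Kncn at 3.95 and Grxcr2 at 3.55, and of the synapse list 8 of 17 rose (10 adjusted over the list alone), with Pvalb at 4.70. Camera adjusted p-values were 7.56e-10, 9.83e-21 and 1.34e-12, with adjusted p = 0.0779, 0.121 and 0.115 with an estimated correlation. Fry called all 3 lists higher (adjusted p = 0.00318, 0.0232 and 0.00832). Of the cell cycle list 31 of 34 fell (33 adjusted over the list alone), led by Ccnb1 (-4.32), Ube2c (-4.25) and Ccnb2 (-4.02). That list kept its call with an estimated correlation (adjusted p = 0.01). Of the Notch list 2 of 16 genes rose and 5 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.0408, with an estimated correlation adjusted p = 0.603). Cdkn1c, a cell cycle inhibitor, rose (1427 against 43.5 TPM; log2 difference 4.98), as did Ccl21b (4.96), Nefm (3.64) and Otoa (4.11), and Heyl (-4.66), Ache (-4.51), Hist1h2ap (-4.64), Uhrf1 (-3.28), Lgr6 (-2.55), Col1a1 (-2.04), Tek (-2.17) and Gata2 (-2.58) fell. Cib3, listed at 0 at D0, was at 78.5 ± 91.5 TPM at D4. Of the neuron list 1 of 10 rose (3 adjusted over the list alone), and of the Wnt list 1 of 17 fell (5 adjusted over the list alone). Camera called these lists and the stress list, 0 of 16 (adjusted p = 0.00234, 0.0431 and 0.0228, with adjusted p = 0.121, 0.603 and 0.603 with an estimated correlation). Of these 3 lists fry called only the neuron list (adjusted p = 0.043, 0.149 and 0.439). Of 33 genes called among those named by rule, 8 kept the call in every fit without 1 of these libraries. The count was 223 without replicate 1 and 223 without replicate 2 of LCP D0, and 183 without replicate 2 of LCP D4. Without replicate 1 of LCP D4 the calls split into 345 higher and 284 lower. The count was 994 with the replicate block (325 higher and 669 lower) and 0 in a fit of these 4 libraries alone (3028 genes had an unadjusted p under 0.05 by limma in the fit of 18 libraries).

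LCP D10 was compared with D0 in the same way. Cabp2 rose by a log2 difference of 9.24 from D0 (SE 1.02, adjusted p = 3.54e-04) and Kcna10 by 8.06 (SE 0.77, adjusted p = 1.65e-04). Gfi1, a hair cell transcription factor, rose by 5.93 (SE 0.59, adjusted p = 1.91e-04), and Otof, which encodes the calcium sensor otoferlin, by 5.61 (SE 0.77, adjusted p = 0.00143). Cdk1 and Ccnb1, drivers of mitosis, fell, with log2 differences of -5.98 (SE 0.54, adjusted p = 1.55e-04) and -5.48 (SE 0.40, adjusted p = 6.21e-05). Atoh1, at 19.3 ± 7.14 TPM, was at a log2 difference of 1.96 (SE 0.69, adjusted p = 0.123) and did not pass. Of 1512 genes past the threshold, 624 were higher and 888 lower at D10.

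Of the hair cell lists, 5 of 10 transcription factors (6 adjusted over the list alone), 23 of 34 bundle genes (27 higher and 1 lower adjusted over the list alone) and 12 of 17 synapse genes (13 adjusted over the list alone) rose. Their camera adjusted p-values were 5.8e-06, 9.15e-22 and 3.23e-15, with adjusted p = 0.115, 0.115 and 0.107 with an estimated correlation. Kncn, Fscn2 and Lhfpl5 rose by 5.73, 5.45 and 5.39, and Calb1, a calcium buffer, was at a log2 difference of 1.09 (adjusted p = 0.268). Of the cell cycle list 32 of 34 fell (33 adjusted over the list alone), and the list kept its call with an estimated correlation (adjusted p = 0.0134). Of the Notch list 1 of 16 rose and 7 fell (1 and 8 adjusted over the list alone; camera adjusted p = 0.002, with an estimated correlation adjusted p = 0.338), with Hes1 at -6.22, Hes5 at -5.38 and Heyl at -5.31. Of the chromatin regulators 7 of 25 fell (8 adjusted over the list alone), with Uhrf1 at -4.37, Ezh2, the Polycomb methyltransferase gene, at -1.95 and Dnmt3b at -1.56 (camera adjusted p = 0.002, with an estimated correlation adjusted p = 0.338). Of the Wnt list 3 of 17 fell (5 adjusted over the list alone), namely Ccnd1 (-2.92), Tcf7 (-2.92) and Lgr6 (-2.25). Its camera adjusted p was 0.0171, with adjusted p = 0.474 with an estimated correlation. Of the neuron list 2 of 10 rose (5 adjusted over the list alone), the neurofilament genes Nefl (5.06) and Nefm (4.48). Its camera adjusted p was 0.00181, with adjusted p = 0.115 with an estimated correlation. The stress list was higher by camera with 0 of 16 members past the threshold (adjusted p = 0.00816, with an estimated correlation adjusted p = 0.474). Drc1 (5.99), Cxcl14 (5.78), S100a1 (2.94) and Otoa (3.83) also rose, and Hist1h2ap (-6.28), Pbk (-5.43), Ngfr (-1.19), Col1a1 (-2.29), Tek (-2.39) and Gata2 (-2.67) fell. Cib3, listed at 0 at D0, was at 426 ± 557 TPM at D10.

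Lgr5 differed widely between the D10 replicates, at 33 ± 40.8 TPM, and so did Cabp2, at 1008 ± 1131 TPM. Of 36 genes called among those named by rule, 22 kept the call in every fit without 1 of these libraries. Leaving out replicate 2 of LCP D10 gave 829 genes, leaving out D0 replicate 1 or 2 gave 479 or 597, and a fit of these 4 libraries alone gave 0 (4202 genes had an unadjusted p under 0.05 by limma in the fit of 18 libraries). With median ratio scaling the calls split into 796 higher and 704 lower, and the replicate block gave 2009 calls, 767 higher and 1242 lower. The date covariate, the only fit that compares groups within dates, gave 1656 calls, 525 higher and 1131 lower. Of these, 1221 were among the calls of the main fit.

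**Figure D2:**
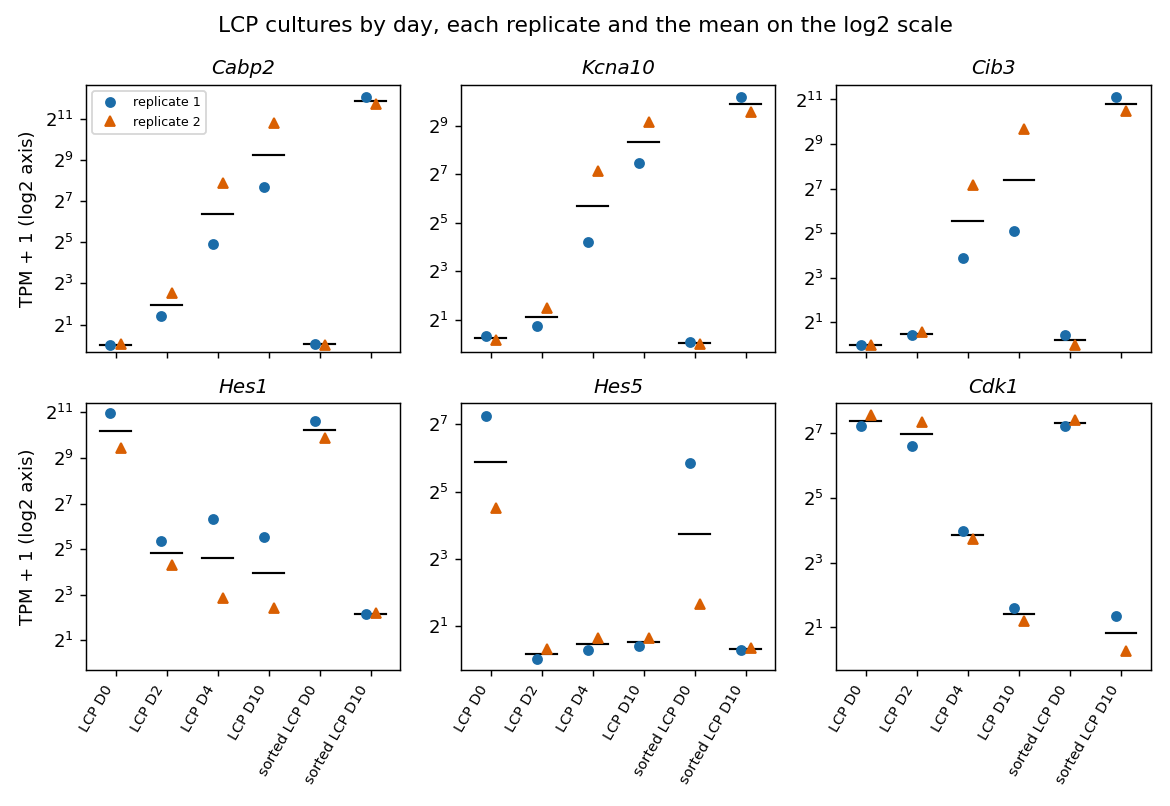
TPM + 1 on a log2 axis for Cabp2, Kcna10, Cib3, Hes1, Hes5 and Cdk1 in LCP cultures by day. Circles are replicate 1, triangles replicate 2, and bars the mean on the log2 scale of the 2 replicates. The arithmetic mean of Cabp2, which the bars do not show, goes from 0.021 TPM at unsorted D0 to 1008 at unsorted D10 and 3806 at sorted D10.

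In the sorted cultures D10 was compared with D0. Cabp2 rose to 3806 ± 629 TPM (log2 difference 11.85, SE 1.02, adjusted p = 5.09e-05). Spp1, which encodes the secreted protein osteopontin, rose from 22.1 ± 26.1 to 10280 ± 3467 TPM (log2 difference 9.50, SE 1.51, adjusted p = 0.00107). Atoh1 and Pou4f3 rose by 4.55 (SE 0.69, adjusted p = 8.14e-04) and 5.72 (SE 0.69, adjusted p = 2.47e-04), and Myo7a, a hair bundle myosin, by 5.25 (SE 0.61, adjusted p = 1.89e-04). Hes1 and Cdk1 fell, with log2 differences of -8.08 (SE 1.24, adjusted p = 8.65e-04) and -6.49 (SE 0.54, adjusted p = 4.39e-05). Of 4911 genes past the threshold, 2727 were higher and 2184 lower at D10. The balance depends on the fit: it was 2472 higher and 2898 lower with quantile normalization, 1565 and 1948 without replicate 2 of sorted LCP D0, and 1920 and 2096 among protein-coding genes tested alone, an alternative chosen after seeing the data.

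Of the hair cell lists, 6 of 10 transcription factors (6 adjusted over the list alone), 29 of 34 bundle genes (30 adjusted over the list alone) and 15 of 17 synapse genes (15 adjusted over the list alone) rose. Their camera adjusted p-values were 0.000132, 8.27e-20 and 6.77e-13, with adjusted p = 0.18, 0.18 and 0.163 with an estimated correlation. Gfi1 (7.47), Lhx3 (7.02), Lhfpl5 (7.71), Kncn (7.44), Fscn2 (6.86) and Calb2 (7.31) were among them. Of the cell cycle list 33 of 34 fell (34 adjusted over the list alone; with an estimated correlation adjusted p = 0.0437). Of the Wnt list 7 of 17 fell (9 adjusted over the list alone), including Ccnd1 (-5.13), Lgr6 (-4.62) and Tcf7 (-4.29). Its camera adjusted p was 2.18e-05, with adjusted p = 0.18 with an estimated correlation. Of the Notch list 3 of 16 rose and 6 fell (3 and 7 adjusted over the list alone), with Nrarp at -4.83 and Hey1 at -4.52. Its camera adjusted p was 0.0464, with adjusted p = 0.538 with an estimated correlation. Of the neuron list 5 of 10 rose (5 adjusted over the list alone; camera adjusted p = 0.0154, with an estimated correlation adjusted p = 0.18), with Nefl at 6.78 and Nefm at 6.50. Chromatin regulators went both ways, with 2 of 25 higher and 6 lower (2 and 6 adjusted over the list alone), Uhrf1 at -4.66, Ezh2 at -2.07 and Dnmt1 at -1.73. Cib3 (10.57), Kcna10 (9.84), Cxcl14 (9.00) and Smpx (8.83) rose further, and Hells (-7.10), Mir686 (-6.94), Hist1h2ap (-6.24), Lgals1 (-5.94), Lum (-4.82), Dcn (-3.92), Epyc (-3.57) and Sox10 (-2.71) fell. Lum and Dcn belong to the mesenchyme list, of which 4 of 10 fell (4 adjusted over the list alone), and Sox10 to the glia list, of which 2 of 7 fell (2 adjusted over the list alone). Camera called neither (adjusted p = 0.0784 and 0.0783), while fry called both lower (adjusted p = 0.0169 and 0.00606). Of the supporting cell list, with Epyc, 2 of 22 rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.207). Of 47 genes called among those named by rule, 39 kept the call in every fit without 1 of these libraries. The count was 2440 without replicate 1 of sorted LCP D10 and 2032 in a fit of these 4 libraries alone.

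The genes separating the native sorts were followed in the cultures. Of 59 genes higher in native hair cells by a log2 difference of at least 1, 17 rose and 0 fell in sorted LCP D10 against D0, with a median log2 difference of 0.20 (camera adjusted p = 0.000618, with an estimated correlation adjusted p = 0.0887). Of these 59 genes, 23 passed against the Lgr5 sort alone and 43 against the Sox2 sort alone. Slc26a5 was the only member of the 3 hair cell lists called in the native comparison, so the set holds little of them. A further 101 genes were higher in native supporting cells at this size. Of those, 31 passed against the Lgr5 sort alone and 70 against the Sox2 sort alone, so both sets lean on the Sox2 sort. Of these 101 genes, 3 rose and 40 fell, with a median of -0.52 (camera adjusted p = 9.33e-08, with an estimated correlation adjusted p = 0.0655). In the unsorted cultures the 59 genes gave 8 higher and 2 lower (median 0.04, camera adjusted p = 0.00333, with an estimated correlation adjusted p = 0.109). The 101 genes gave 1 higher and 14 lower there (median -0.07, camera adjusted p = 0.0115, with an estimated correlation adjusted p = 0.216). The alternatives set beforehand called the native genes anew. With a pseudocount of 0.1 only 28 genes were higher in native hair cells, and these were not called in unsorted cultures (adjusted p = 0.13). With the same 59 genes, a test chosen after seeing the data, the call stayed with that pseudocount (adjusted p = 0.000858) and with the replicate block (0.00405). With the same 101 genes the block gave 1 higher and 17 lower in unsorted and 3 higher and 41 lower in sorted cultures (adjusted p = 0.0248 and 5.46e-07).

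The sort itself was examined at D0. Few genes differed: 16 passed, 6 higher and 10 lower in the sorted cells, and 1948 had an unadjusted p under 0.05 by limma. Ppme1, a protein phosphatase methylesterase gene, was lower in sorted LCP D0 (17.9 against 119 TPM; log2 difference -2.62, SE 0.40, adjusted p = 0.0477), and n-R5s188, a 5S ribosomal RNA gene listed at 0 in unsorted cells, was at 21.5 TPM. The near-identical microRNA genes Mir1906-1 and Mir1906-2 were listed at 0 in sorted and 31.2 TPM each in unsorted cells (adjusted p = 0.0545 with the replicate block). Lgr5 was at 48.3 ± 62.5 TPM in sorted and 89.1 ± 31.7 in unsorted cells (log2 difference -1.99, SE 1.25, adjusted p = 0.596). No member of the 17 lists passed and camera called none of them. The median of all genes was shifted by -0.118 on the log2 scale. Of 4 genes called among those named by rule, 1 kept the call in every fit without 1 of these libraries. With the replicate block 25 genes passed. The count was 238 without replicate 1 and 25 without replicate 2 of sorted LCP D0 (13 higher and 12 lower), 8 without replicate 2 of unsorted LCP D0, and 0 in a fit of these 4 libraries alone.

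Sorted and unsorted cultures were compared at D10. Bundle genes Loxhd1 (log2 difference 2.38, SE 0.54, adjusted p = 0.0257), Myo15 (2.16, SE 0.55, adjusted p = 0.0414) and Cdh23, a tip link cadherin (1.82, SE 0.44, adjusted p = 0.0331), were higher in the sorted cells. So was the calcium channel gene Cacna1d (1.79, SE 0.38, adjusted p = 0.0199). The extracellular matrix genes Lum (-3.98, SE 0.72, adjusted p = 0.0127), Epyc (-4.16, SE 0.92, adjusted p = 0.0234) and Mgp (-3.83, SE 0.69, adjusted p = 0.0124) were lower. Lgr6, a Wnt pathway receptor, was lower (-2.73, SE 0.53, adjusted p = 0.0156). Of 1273 genes past the threshold, 877 were higher and 396 lower in the sorted cells, while of the protein-coding genes among them 250 were higher and 364 lower.

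Short RNA genes made up 193 of the higher and 7 of the lower genes, and genes of other types, neither protein-coding nor short RNA, 434 and 25. Protein-coding genes tested alone, an alternative chosen after seeing the data, gave 219 higher and 306 lower. Mir5128 was higher by 4.44, and Mir8090, Mir5098, Mir6362, Mir6955 and Snord61, listed at 0 in the unsorted cells, were at 46.6, 45.3, 38.5, 21.8 and 24.2 TPM. Nupr1 (-5.52), Lgals1 (-4.63), Dcn (-2.56) and Blnk (-3.61) were lower, and Ntrk3 (1.36) was higher. Lum and Dcn are the 2 of 10 mesenchyme markers past the threshold (2 adjusted over the list alone; camera adjusted p = 0.0689). Of the bundle list 3 of 34 were higher (5 adjusted over the list alone) and of the synapse list 1 of 17 (2 adjusted over the list alone). Camera adjusted p-values were 1.21e-05 and 0.000245, with adjusted p = 0.608 and 0.513 with an estimated correlation. The Wnt list was lower (1 of 17, 1 adjusted over the list alone; camera adjusted p = 8.34e-05, with an estimated correlation adjusted p = 0.513). The stress list was lower (0 of 16; camera adjusted p = 0.0154, with an estimated correlation adjusted p = 0.608). Of 19 genes called among those named by rule, 1 kept the call in every fit without 1 of these libraries. With the replicate block 2434 genes passed, 1284 higher and 1150 lower, and with quantile normalization the calls split into 785 higher and 766 lower. The count was 56 without replicate 1 and 2461 without replicate 2 of LCP D10, 93 and 292 without replicate 1 and 2 of sorted LCP D10, and 0 in a fit of these 4 libraries alone (4847 genes had an unadjusted p under 0.05 by limma in the fit of 18 libraries).

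The change from D0 to D10 was tested for a difference between sorted and unsorted cultures. It differed for 42 genes, 34 with a higher and 8 with a lower change in the sorted cells. The change in Cabp2 differed by 2.61 (SE 1.45, adjusted p = 0.537) and that in Atoh1 by 2.59 (SE 0.98, adjusted p = 0.359), neither past the threshold. Camera gave a larger change in sorted cells for the bundle and synapse lists and a lower one for the Wnt and stress lists, with 0 members past the threshold in each (adjusted p = 8.87e-07, 8.51e-05, 8.51e-05 and 0.00737). For each of the 4 lists adjusted p = 0.614 with an estimated correlation. The median of all genes was shifted by 0.182. The count was 352 without replicate 2 of LCP D10, 21 without its replicate 1, 27 without replicate 1 of LCP D0, and 0 among protein-coding genes tested alone, an alternative chosen after seeing the data.

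Sorted LCP D10 was then set beside native hair cells. Calb1, an abundant calcium buffer of native hair cells, was at 2.58 ± 1.14 TPM in the cultures and 948 ± 555 in the Atoh1 sort (log2 difference -7.95, SE 0.52, adjusted p = 6.27e-06). Slc26a5 was lower in the cultures (0.321 ± 0.327 TPM; log2 difference -3.63, SE 0.42, adjusted p = 2.93e-04). Cib3 (1803 ± 555 against 0.344 ± 0.112 TPM), which encodes a calcium and integrin binding protein, was higher by 10.36 (adjusted p = 3.10e-04), and Cabp2 by 4.57 (SE 1.02, adjusted p = 0.0143). Atoh1, Pou4f3 and Myo7a were at log2 differences of -2.13 (adjusted p = 0.0677), -0.41 (adjusted p = 0.767) and -0.91 (adjusted p = 0.376) and did not pass, though Atoh1 did with the replicate block (adjusted p = 0.0497). Of 2424 genes past the threshold, 922 were higher and 1502 lower in the cultures.

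Of the hair cell lists, 0 transcription factors were higher and 4 of 10 lower (0 and 5 adjusted over the list alone), 1 of 34 bundle genes was higher and 3 lower (1 and 3 adjusted over the list alone), and 4 of 17 synapse genes were higher and 5 lower (4 and 5 adjusted over the list alone). The transcription factor list was lower by camera (adjusted p = 0.0373; with an estimated correlation adjusted p = 0.575), with Insm1 at -2.56, Hes6 at -2.53 and Barhl1 at -2.34. Myo3a (-3.35), Whrn (-2.46) and Gpsm2 (-1.99) were the lower bundle genes. Of the supporting cell list 1 of 22 was higher and 5 lower (1 and 6 adjusted over the list alone), with Fabp7 at -6.81, Tectb at -6.60 and Fgfr3 at -5.50. Its camera adjusted p was 0.0308, with adjusted p = 0.575 with an estimated correlation. Of the Notch list 4 of 16 were lower (7 adjusted over the list alone; camera adjusted p = 0.00857, with an estimated correlation adjusted p = 0.575), with Hes5 at -7.01, Jag1 at -4.29 and Nrarp at -3.44. Fabp7, Tectb and Hes5 were at 152.5, 387.2 and 196.6 TPM in the Atoh1 sort. Other cells within that sort therefore cannot be told apart from a difference in the hair cells. Hemoglobin genes of the erythroid list were lower in the cultures, 4 of 5 members (4 adjusted over the list alone), Hbb-bs being listed at 0 in the cultures and at 97.7 TPM in the Atoh1 sort (camera adjusted p = 0.00476, with an estimated correlation adjusted p = 0.575). So were 4 of 10 mesenchyme markers (4 adjusted over the list alone), with Col3a1 at -6.38 and Col1a2 at -4.85 (camera adjusted p = 0.00255, with an estimated correlation adjusted p = 0.395). Spp1 (9.41), Lce6a (8.89), Car9 (7.38), Neat1 (7.31) and Dhrs3 (7.19) were higher in the cultures, and Otor (-7.85), Oc90 (-4.79), Lmo3 (-4.36), Mcm2 (-3.33) and Elavl4 (-3.00) were lower. Of the cell cycle list 5 of 34 were lower (9 adjusted over the list alone; camera adjusted p = 0.00476, with an estimated correlation adjusted p = 0.575). Of 43 genes called among those named by rule, 22 kept the call in every fit without 1 of these libraries. The median of all genes was shifted by -0.109, and with median ratio scaling the calls split into 1313 higher and 1142 lower. The count was 1226 and 1013 without replicate 1 and 2 of the Atoh1 sort, 1154 and 941 without replicate 1 and 2 of sorted LCP D10, and 963 in a fit of these 4 libraries alone.

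Sorted LCP D0 was set beside the native Lgr5 sort. Cell cycle genes were higher in culture: Cdk1 was at 158 ± 14.3 TPM against 2.86 ± 1.35 (log2 difference 5.41, SE 0.54, adjusted p = 1.06e-04). Cdc20 (5.30, SE 0.69, adjusted p = 5.46e-04) and Ccnb1 (5.26, SE 0.40, adjusted p = 2.01e-05) were higher as well. Hair cell genes were lower in culture, with Atoh1 at a log2 difference of -5.33 (SE 0.69, adjusted p = 5.14e-04) and Lhfpl5 at -7.66 (SE 0.88, adjusted p = 2.36e-04). The Lgr5 sort itself held hair cell transcripts, with Lhfpl5 at 297.8 TPM. Hair cells within this reference therefore cannot be told apart from a loss in the cultured cells. Tectb, a tectorial membrane gene, was lower (12.9 against 2980 TPM; log2 difference -8.23, SE 1.21, adjusted p = 0.00115), and Aldh1a3, a retinoic acid synthesis gene, was higher (548 against 2.67 TPM; 6.96, SE 0.57, adjusted p = 2.90e-05). Of 2242 genes past the threshold, 788 were higher and 1454 lower in culture.

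Of the cell cycle list 30 of 34 were higher (31 adjusted over the list alone; with an estimated correlation adjusted p = 0.0146). Of the hair cell lists, 8 of 10 transcription factors (8 lower and 1 higher adjusted over the list alone), 27 of 34 bundle genes (30 adjusted over the list alone) and 13 of 17 synapse genes (14 adjusted over the list alone) were lower. Their camera adjusted p-values were 1.33e-07, 4.86e-23 and 2.84e-15, with adjusted p = 0.105, 0.121 and 0.105 with an estimated correlation. Of the supporting cell list 7 of 22 were lower (7 adjusted over the list alone), with Fabp7 at -7.06 and Fgfr3 at -5.91 (camera adjusted p = 0.000218, with an estimated correlation adjusted p = 0.275). Of the Wnt list 4 of 17 were higher and 1 lower (4 and 1 adjusted over the list alone), with Ccnd1 at 3.21, Tcf7 at 2.50 and Fzd9 at -3.24 (camera adjusted p = 0.0218, with an estimated correlation adjusted p = 0.444). Of the chromatin regulators 3 of 25 were higher (3 adjusted over the list alone), Uhrf1 (3.38), Ezh2 (1.90) and Dnmt1 (0.90). Hspb1 (5.60), Acox2 (5.34), Pbk (5.30) and Dcn (2.88) were also higher, and Defb25 (-8.55), Calb1 (-8.23), Ccer2 (-8.22), Fcrlb (-8.15), Chrna9 (-7.04), Hes5 (-5.61), Jag2 (-3.01), Nefl (-5.56) and Col3a1 (-4.41) were lower. Of the neuron list 4 of 10 and of the list of other cochlear epithelium markers 3 of 9 were lower (6 lower, and 4 lower and 1 higher, adjusted over the list alone; camera adjusted p = 0.0136 and 0.0462, with adjusted p = 0.205 and 0.273 with an estimated correlation). Of 48 genes called among those named by rule, 36 kept the call in every fit without 1 of these libraries. With quantile normalization the calls split into 1109 higher and 1223 lower. The count was 1113 without replicate 2 of the Lgr5 sort, 1407 without replicate 2 of sorted LCP D0, and 0 in a fit of these 4 libraries alone (4698 genes had an unadjusted p under 0.05 by limma in the fit of 18 libraries).

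**Figure D3:**
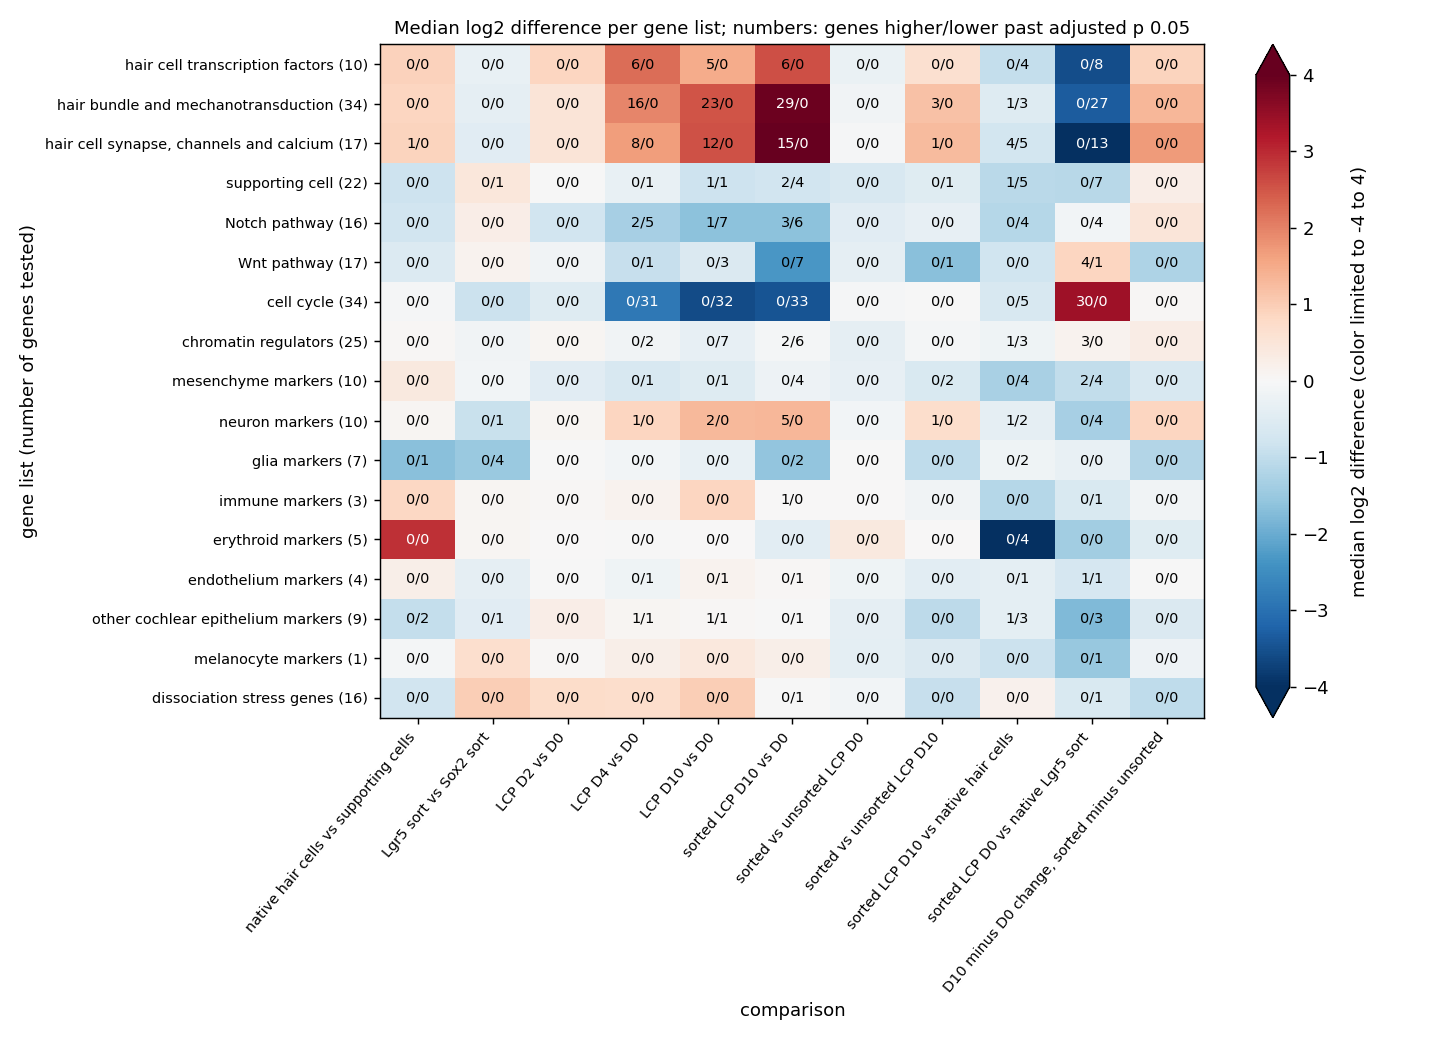
Median log2 difference (color) of each of 17 gene lists, in rows with the number of genes tested, in the 11 comparisons, in columns. The numbers in each cell are the genes higher and lower past an adjusted p of 0.05; the cell cycle row holds 31, 32 and 33 lower genes in LCP D4, LCP D10 and sorted LCP D10 against D0.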

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

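The tests on hair cell transcripts in the supporting cell sorts and on LCP D10 replicate 1 were chosen only after the result was seen, and so was the requirement, added to the tests on glial genes, that replicate pairs go the same way.

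The change from D0 to D10 differed between sorted and unsorted LCP cultures for 42 genes, 34 higher and 8 lower in the sorted cells, by a test of the difference itself. Of these, 10 were protein-coding, 11 microRNA, 6 snRNA, 4 rRNA, 3 snoRNA and 2 scaRNA genes. Listing at 0 in several groups can lower the shared spread of such short genes. The microRNA gene Gm26302, for example, was listed at 0 in sorted LCP D0 and in unsorted LCP D0 and D10. Its SE was 0.246, against 0.977 for Atoh1. Among the coding genes, named after their values were seen, Tnni3 (log2 4.36, adjusted p = 0.0492), Mcub (2.65) and Kcnj6 (1.86) were higher. Blnk (-4.57), Rbpms (-3.90), Selenop (-2.84), Mmp14 (-2.29) and Timp2 (-2.18) were lower. These calls end among protein-coding genes tested alone, chosen after seeing the data, and at a filter of 5 TPM, each with 0 genes passing (2267 had an unadjusted p under 0.05 by limma over all genes).

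Hair cell transcripts were present in the native supporting cell sorts: over 36 of the 61 listed hair cell genes, those at 10 TPM or more in the Atoh1 sort and under 1 in sorted LCP D0, the median log2 difference of these sorts from the Atoh1 sort was -1.003 (range -1.82 to -0.41). If hair cells lie within these sorts, the difference should be nearly one factor for all genes. The SD across the genes was 0.306, which is 0.577 times the SD of 0.53 between the Atoh1 sort's own replicates. The first SD is of group means and the second of single libraries, so noise alone gives a ratio below 1. The ratio of 0.577 thus does not show that one factor holds, and it leaves room for differences between genes. Hair cells within the sorts may account for the pattern. Over the 25 genes left out the median was -0.802 (range -1.13 to 0.64) and the SD ratio 0.962, and over all 61 this ratio was 0.79. Of these 25 genes, 20 were at 1 TPM or more in sorted LCP D0. The 36 genes were thus chosen in part for being low in cultured cells, and the lower ratio holds for them alone. Doublets or free hair cell RNA would also give one factor and stay open. A supporting cell fraction in the Atoh1 sort would change the size of the factor, but would not put hair cell transcripts into the other sorts. Expression of these transcripts by supporting cells themselves was tested only through the SD ratio, which does not exclude it.

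Hair cell transcripts were lower in LCP D10 replicate 1 than in replicate 2, by a median log2 difference of 0.59 over 61 genes, 52 of them in that direction. Sequencing date cannot be told apart from this. Of the 5 other groups on these dates, the Atoh1, Lgr5 and Sox2 sorts shifted the same way (0.461, 0.575 and 0.249), sorted LCP D10 the other way (-0.473), and sorted LCP D0 little (-0.095). A smaller share of the same hair cells may also account for it, but the bundle and synapse genes (median 0.667) exceeded 5 transcription factors (-0.095) by 0.762, with a permutation p of 0.0903 that leaves this undecided. Of the 5, Pou4f3 (0.932) and Gfi1 (0.832) followed the pattern and Atoh1 (-0.735) and Barhl1 (-0.654) went the other way; a difference in maturation between the cultures was not tested.

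Glial transcripts were higher in the Sox2 sort than in the Lgr5 sort. A second list of 19 myelin and Schwann cell genes, written before its values were seen, had 15 tested, higher by a median log2 difference of 1.187 (14 genes above 0, lowest replicate pair 0.966), of which Prx, Cldn19 and Sostdc1 passed singly (10.6 against 0.34, 8.47 against 0.09 and 36.9 against 4.94 TPM). Glial RNA free in all native preparations was argued against, since the list was also higher than in the Atoh1 sort by 1.822 (lowest replicate pair 1.197). Glial cells that carry the Sox2 sort's marker are a candidate source, but the difference is not limited to glia: neuron markers (camera adjusted p = 5.26e-07, with an estimated correlation adjusted p = 0.0239) and other cochlear epithelium markers (0.00632 and 0.232) were higher in the Sox2 sort too. A difference between the supporting cell populations that the sorts hold was not tested.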

How the results depend on the processing

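Depth is unknown for TPM values, so its effect could not be tested. The protein-coding, single-sort and same native genes alternatives were chosen after seeing the data; the others were set before. Where 1 replicate was left out, the lone sample was assumed to vary like the other groups. No call of a named gene or gene list was found with the opposite direction. The larger side of the calls did turn in 8 comparisons, and those splits stand in the report. The cause of a change was not tested, except that the fit of the compared groups alone has fewer samples, and filters and gene types change which genes are tested.

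Counts that moved by over 1.5 times are given here in the order of the report. Native hair cells against supporting cells (168 genes) gave 105 with a pseudocount of 0.1, 352 with no filter, 53 with TPM of at least 5, 365 with array weights, 10 with the groups alone and 63 against the Lgr5 sort alone. The Lgr5 against the Sox2 sort (114) gave 30 with a pseudocount of 0.1, 232 with no filter, 19 with TPM of at least 5, 73 with the sequencing date and 0 with the groups alone. LCP D2 (10) gave 22 with no filter, 0 with TPM of at least 5, 6 with the date, 20 with array weights and 0 with the groups alone. With the replicate block D2, D4 and D10 gave 12, 994 and 2009. LCP D4 (693) gave 1148 with the date and 0 with the groups alone, LCP D10 (1512) gave 0 and sorted LCP D10 (4911) gave 2032 with the groups alone. Sorted against unsorted D0 (16) gave 35 with no filter, 5 with TPM of at least 5, 25 with the replicate block, 10 with the date, 2 among protein-coding genes and 0 with the groups alone. Sorted against unsorted D10 (1273) gave 804 with a pseudocount of 0.1, 2164 with no filter, 750 with TPM of at least 5, 2434 with the block, 2674 with the date, 525 among protein-coding genes and 0 with the groups alone. Sorted LCP D10 against native hair cells (2424) gave 3679 with the date, 4291 with array weights and 963 with the groups alone, and sorted LCP D0 against the Lgr5 sort (2242) gave 0. The difference of changes (42) gave 27 with a pseudocount of 0.1, 144 with no filter, 0 with TPM of at least 5, 22 with the date, 20 with array weights and 0 among protein-coding genes. The other alternatives listed for the processing stayed within 1.5 times.

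Leaving out 1 library gave 73 to 194 genes for native hair cells against supporting cells, 45 to 285 for the Lgr5 against the Sox2 sort, 2 to 14 for D2, 183 to 629 for D4, 479 to 1392 for D10 and 2440 to 4101 for sorted LCP D10. It gave 8 to 238 for the sort at D0, 56 to 2461 for the sort at D10, 941 to 1226 and 1113 to 2154 for the comparisons of sorted LCP D10 and D0 with native sorts, and 21 to 352 for the difference of changes. The extremes rest on LCP D10 for the sort at D10 and the difference of changes (56 without replicate 1, 2461 and 352 without replicate 2) and for the sort at D0 the highest rests on sorted LCP D0 (238 without replicate 1) and the lowest on unsorted LCP D0 (8 without replicate 2).

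With an estimated correlation the 4 tests of native genes lost their call, with medians unchanged at 0.04, -0.073, 0.196 and -0.515 (adjusted p = 0.109, 0.216, 0.0887 and 0.0655). The native hair cell genes in unsorted cultures lost it also with a pseudocount of 0.1 (median 0 over 28 genes called anew). The other 3 medians were then -0.286, 0.466 and -1.311, and with the replicate block, over 66 and 152 genes called anew, the 4 medians were 0.057, -0.115, 0.195 and -1.036. With the same native genes all calls stayed, with medians of 0.263, -0.259, 0.799 and -1.072 with the pseudocount and unchanged with the block. Of 187 list tests, 58 lost their call with an estimated correlation and 30 with fry, which gained 9, and 1 gained it with the replicate block. Of 256 calls of named genes, 116 were lost in some fit without 1 library.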

Other observations

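Some tests in this part were completed after the result was seen: the requirement that list members and replicate pairs go the same way was added then, while the lists and their bounds were written before their values were seen.

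Genes of glycolysis and of the response to low oxygen were higher in the sorted LCP D10 cultures than in native hair cells. Of 20 listed genes 12 were higher and 1, Pfkfb4 (log2 difference -1.37, adjusted p = 0.0458), was lower. Bnip3, a mitophagy gene induced by low oxygen, was at 1368 TPM in the cultures and 55 in the Atoh1 sort (log2 difference 4.61, SE 0.90, adjusted p = 0.0072). Vegfa (log2 difference 3.44), Pgk1 (2.91), Ldha (2.47) and Aldoa (2.13) were higher too. In unsorted LCP D10 Bnip3 was at 795 TPM and Ldha at 786, against 964 for Ldha in sorted LCP D10 and 175 in the Atoh1 sort.

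A low oxygen response in the cultures was tested as a hypothesis for part of the genes that stand apart from native hair cells. The list's median log2 difference was 2.208 (replicate pairs 2.08 to 2.51), its camera adjusted p over the 2 lists tested was 6.58e-11, and with an estimated correlation adjusted p = 0.0458. The day and the sort were looked at after this. In sorted LCP D0 the members went both ways against the Atoh1 sort (10 of 20 above 0, median 0.175), with Bnip3 at 60.4 TPM, Hk2 at 12.3 against 1.26 and Ankrd37 at 4.21 against 29.9. From sorted LCP D0 to D10 the median difference was 1.779, with 11 genes higher and 0 lower past the threshold. Unsorted LCP D0 was already apart from the Atoh1 sort (2.187), with 17 of 20 genes above 0, and from unsorted D0 to D10 the members again went both ways (9 above 0, median -0.082, replicate pairs -1.23 to 0.66). The difference of 2.208 is consistent with a low oxygen response, but glycolysis may differ for other reasons, and what part culture, day and sort each have stays open.

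A second hypothesis was that the hair cells in culture may resemble vestibular hair cells, the hair cells of the balance organs. A list of 7 vestibular hair cell genes had a median log2 difference of -0.654 in sorted LCP D10 against the Atoh1 sort (replicate pairs -0.82 to -0.26; camera adjusted p = 0.794, with an estimated correlation adjusted p = 0.893). By the bound written beforehand, a median under 0.5, this counts against the hypothesis. However, Mapt (4.53) and Meis2 (4.94) were higher and Tnc (-2.98) was lower, so a median over members that go both ways decides little, and the question stays open.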
